A study of Mus musculus with 9 samples.

How the data were processed

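RNA abundance was measured in 9 samples from mice at postnatal day 13, in 3 groups of 3. Per the labels, the groups were wildtype cerebellum, Sufu KO cerebellum and Ptch1 KO medulloblastoma. Per the labels' protocols, the tissue was dissected, frozen and extracted for total RNA with a column kit, and biotin-labelled material was hybridised to Affymetrix Mouse Gene 1.0 ST arrays by the manufacturer's standard procedure. Groups and replicate numbers were taken from the labels of each sample. The labels do not say that the samples of a group came from separate animals, so p-values measure the spread between these samples, which may be partly technical. Each mutant group held 1 array with high Xist and 2 with high Y-linked genes, so its samples did not all come from 1 animal. All 3 wildtype arrays had high Xist, which leaves a wholly technical spread open for that group.

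The authors deposited a table of log2 expression values, with 1 value for each of 35556 probe sets on each of the 9 arrays. The scale was recognised from the values, whose lowest on each array lay between 3.04 and 3.13 and highest between 13.5 and 13.8. The background correction, normalization and summary method behind these deposited log2 values are not given in the sources used here. The arrays' quartiles lay close together, with the 25th percentiles differing by at most 0.0893 and the medians by at most 0.0647. The values carry no detection calls, so a dim gene cannot be told from background, and folds of dim genes may be understated. No column of per-sample values was left unused, and no pair of arrays held identical values.

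Probe sets were named with the annotation table supplied for this array, with symbols updated by gene identifier through a RefSeq gene table of assembly GRCm38.p6. That table was used for names and for the order of neighbouring genes, and its coordinates are not given. Of the probe sets, 21789 had 1 gene symbol, 1621 had several and 12146 were not listed in the annotation, which leaves them unnamed here. Of the single-gene probe sets 21698 matched the RefSeq table by identifier, and 0 gene symbols changed. Probe sets with several symbols or none entered no comparison. For the 999 genes with several probe sets, the probe set with the highest mean over all 9 arrays stood for the gene. Among such genes called in a comparison, another probe set was called in the opposite direction for 3 of 301 in Sufu KO against wildtype, 8 of 526 in the tumours against wildtype and 2 of 330 between the mutants. Of 19938 genes with a single-gene probe set, 16323 were tested, namely those above their array's 25th percentile on at least 3 arrays.

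Differences between groups were tested with limma 3.58.1 in R 4.3.3. A linear model with 1 mean per group was fitted to the deposited log2 values of all 9 arrays, and variances were moderated with empirical Bayes. The 2-sided p-values were adjusted by the Benjamini-Hochberg method over the genes tested in each comparison, with a threshold of 0.05. Every adjusted p of a gene comes from this fit, with these exceptions. A second probe set of a gene was tested in the same model over all single-gene probe sets, and probe sets of several genes or without annotation over all probe sets. In this text fold is 2 to the power of the log2 difference, SE is the moderated standard error and SD is that of 3 arrays. The median log2 difference of all tested genes was -0.006, -0.013 and -0.008 in the 3 comparisons, so no shift was removed.

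The gene lists for pathways and cell types, the comparisons, the tests, the rule for named genes and most alternatives were fixed before the data were examined. Lists were tested with camera of limma, which compares a list's members with the other genes, with a preset correlation between genes of 0.01. Benjamini-Hochberg adjustment ran over the lists of a comparison. The same test with an estimated correlation and fry, which tests a list on its own, stood beside it. Of the 24 lists, 22 had at least 3 tested members. The unipolar brush cell list had 2 tested members, Eomes and Plcb1, and the red blood cell list 2, Alas2 and Slc4a1, so neither was tested as a list. Eomes read -0.01 in Sufu KO and -1.10 in the tumours (log2 difference), Plcb1 -0.10 and -0.19, Alas2 -0.38 and -0.38, and Slc4a1 -0.10 and -0.13. List members without a single-gene probe set are not reported.

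Genes named in the text followed a rule. Sufu, Ptch1, Spop, Gli1 and Gli2 are always named. In each comparison the rule adds the 5 highest and 5 lowest log2 differences among called genes whose groups do not overlap, leaving out placeholder symbols. For each main list it adds the 3 members with the smallest p, and for each other called list the 2 with the smallest p. The main lists were Hedgehog targets, Hedgehog pathway components, granule neuron progenitor, mature granule neuron, DNA replication and G1/S, and mitosis. Other members may be named where a count is 5 or less. Those members, and any further gene, were chosen after their values were seen.

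Because both mutants were compared with the same wildtype arrays, shared calls were set beside the overlap of independent lists. They were also set beside 100 simulated draws of unchanged groups against those arrays.

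The procedure was tested on simulated data for the comparison of Sufu KO with wildtype over 16323 genes. It recovered 83.6% of 67 genes changed by 0.5 log2 units, 98.5% of 67 changed by 1 and 100% of 66 changed by 2. It called 10 unchanged genes, 5.05% of its calls. In a simulated comparison of the tumours with wildtype, a shifted mitosis list reached adjusted p = 2.38e-37 and camera called 0 of 21 other lists. Simulated genes were drawn independently, so this does not check the list tests where genes are correlated. In the deposited data the estimated correlation was 0.735 for the mitosis list and 0.783 for the mature granule neuron list.

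Alternatives covered quantile normalization, median centring and cyclic loess between arrays, the filter on dim genes, the rule for several probe sets, the arrays in the fit and an intensity-trended robust prior. They also covered array weights, the replicate number as a block, each array left out in turn, stricter thresholds, the other list tests, and the Hedgehog lists without Sufu and Ptch1. A sex covariate, a fit without X and Y chromosome genes and a fit of the 5 arrays with high Xist were added after the uneven spread of sexes was seen. Figures were drawn with matplotlib 3.10.9.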

Results

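Gene expression was measured in the cerebellum of mice at postnatal day 13, a stage at which granule neuron progenitors of the outer layer are finishing their divisions. Total RNA came from 3 groups of 3 samples each, namely wildtype cerebellum, cerebellum of Sufu knockout (KO) mice, and medulloblastoma, a cerebellar tumour, from mice labelled Ptch1 KO. Each sample was hybridised to its own Affymetrix Mouse Gene 1.0 ST array, whose probe sets summarise probes along a gene. The number of arrays, 3 per group, limits the precision of every value. The medians of the 9 arrays lay between 6.72 and 6.79 on the log2 scale. In a principal component analysis the first component carried 77.5% of the variance and the arrays of each genotype lay apart on it. Replicate 3 of the tumours lay nearest to the wildtype on that component, at 26.1 against 41.3 and 39.9 for replicates 1 and 2. Its mean correlation with the wildtype arrays across genes was 0.943, against 0.915 and 0.918. Xist, the RNA that coats the inactive X chromosome of females, was high on all 3 wildtype arrays. It was high on 1 array of each mutant group, and the other 2 arrays of each carried high Y-linked genes.

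The targeted genes and their partners were read first. Sufu encodes a negative regulator of the Hedgehog pathway that binds the Gli transcription factors. Its level was 8.96 ± 0.12 (log2, SD, n = 3) in wildtype and 8.07 ± 0.07 in Sufu KO, a 1.86-fold fall (limma adjusted p = 9.70e-06) with every Sufu KO array below every wildtype array. In the tumours labelled Ptch1 KO, Sufu stood at 9.88 ± 0.06 and was 1.89-fold above wildtype (adjusted p = 9.13e-07). Ptch1, the receptor for Hedgehog ligands and itself a target of the pathway, read 10.26 ± 0.01 in wildtype, 10.20 ± 0.05 in Sufu KO and 11.28 ± 0.14 in the tumours. It rose 2.03-fold in the tumours (adjusted p = 3.69e-07), and its log2 difference in Sufu KO was -0.06 ± 0.08 (SE, adjusted p = 0.607). The labels do not give the deleted part of Ptch1, so this level does not check the Ptch1 KO label, on which every direction given for the tumours rests.

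Spop, the substrate adaptor of a Cullin 3 ubiquitin ligase, fell 1.28-fold in Sufu KO (adjusted p = 0.00684) and 1.30-fold in the tumours (adjusted p = 0.00198). Between the mutants its log2 difference was -0.02 ± 0.08 (SE, adjusted p = 0.896). Gli2, the main activator among the Gli transcription factors, rose 1.92-fold in Sufu KO (adjusted p = 0.000293) and 2.80-fold in the tumours (adjusted p = 1.58e-06). Gli1, a Gli factor whose own transcription the pathway induces, rose 3.51-fold in the tumours (adjusted p = 1.76e-07). In Sufu KO its level was 7.24 ± 0.02 against 7.36 ± 0.14 in wildtype (SD, n = 3), a log2 difference of -0.12 ± 0.12 (SE, adjusted p = 0.537). The amount of Gli2 protein, which the series title names, was not analysed here.

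**Figure D1:**
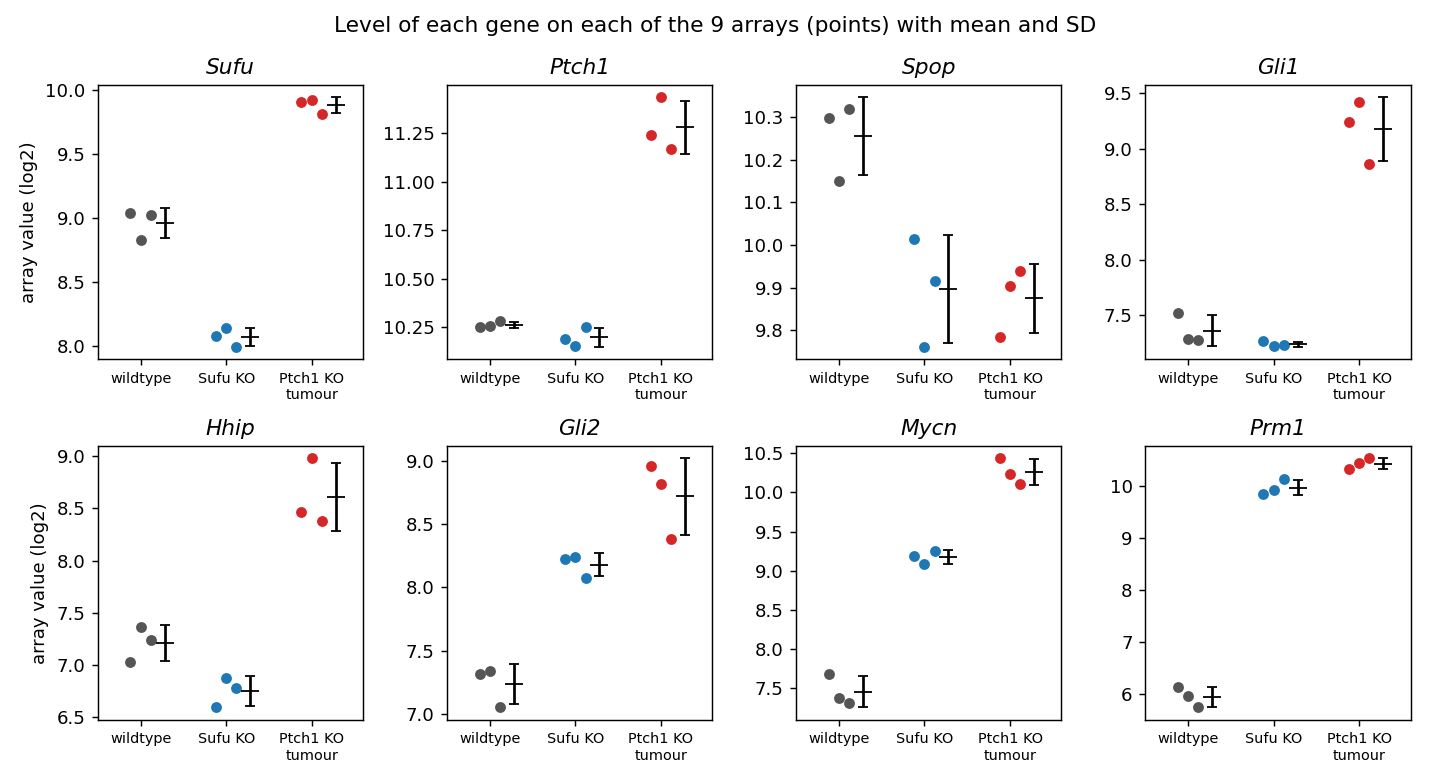
Array value (log2) of 8 genes on each of the 9 arrays, with a panel per gene and its own axis range; points are arrays and the bar beside them is the mean with its SD (n = 3). Gli1 stood at 7.24 in Sufu KO and 9.17 in the tumours, while Gli2 and Mycn were higher than wildtype in both mutants.

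The comparison of Sufu KO with wildtype cerebellum asks how the tissue of the mutant differs at this age. The groups also differed in sex, with high Xist on 3 wildtype arrays and 1 Sufu KO array. The labels give no strain and name no transgene, so these cannot be told apart from loss of Sufu. Genes of dividing cells rose: Mki67, the proliferation marker, rose 6.19-fold (log2 difference 2.63 ± 0.14, SE, n = 3 per group, limma adjusted p = 7.40e-07). Top2a, the topoisomerase that untangles chromosomes before division, rose 5.08-fold (adjusted p = 3.03e-06); a dimmer probe set of Top2a read 0.21 (adjusted p = 0.264). Sfrp1, a secreted Wnt modulator and Hedgehog target, rose 5.07-fold, and Chrna3, a nicotinic acetylcholine receptor subunit, 6.29-fold. Prm1, which encodes the protamine that packs sperm DNA, showed the largest rise, 16.3-fold (4.03 ± 0.11, adjusted p = 1.26e-09). Its chromosomal neighbours Prm2, Prm3 and Tnp2 lay within 0.104 of wildtype on the log2 scale. Among 16323 genes tested, 2122 were higher and 2028 lower in Sufu KO, of which 186 and 36 differed by at least 1 log2 unit.

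The genes that fell furthest included Fam107a, an actin-associated protein of astrocytes, at 3.31-fold lower (log2 difference -1.73 ± 0.25, SE, adjusted p = 0.000339). Gdf10, a growth factor made by Bergmann glia, was 3.16-fold lower (adjusted p = 3.91e-06). Ptpn22, a tyrosine phosphatase of lymphocytes, fell 2.61-fold, and Cntn4, an axonal adhesion molecule, 2.53-fold. Galnt15, an enzyme of O-glycosylation, fell 2.54-fold (adjusted p = 0.0108) with an SD of 0.89 among the Sufu KO arrays. Its call ended without Sufu KO replicate 2 (adjusted p = 0.0502) and with an intensity-trended prior (adjusted p = 0.0657), and over all its alternatives the adjusted p ran from 1.00e-05 to 0.0657.

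All 27 tested genes of mitosis rose in Sufu KO, and also 27 when adjusted over the list alone, with a median log2 difference of 1.77. Tpx2, a spindle assembly factor, rose 3.41-fold and Cenpe, a kinetochore motor, 3.32-fold. The list test (camera) gave adjusted p = 1.80e-29, and adjusted p = 0.138 with an estimated correlation. Of 30 genes of DNA replication and G1/S, 28 rose and 2 did not pass, or 29 risen when adjusted over the list alone. Mcm7 and Mcm5, subunits of the replicative helicase, rose 3.28-fold and 2.40-fold, and E2f1, a transcription factor of S phase entry, 2.55-fold. This list had adjusted p = 6.34e-24, and adjusted p = 0.138 with an estimated correlation.

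Hedgehog targets went both ways in Sufu KO. Of 14 tested, 4 rose, 3 fell and 7 did not pass, with 5 higher and 3 lower when adjusted over the list alone. Those that rose were Sfrp1, the G1 cyclin gene Ccnd2 at 4.53-fold, the kinase gene Cdk6 at 4.01-fold and the growth-promoting transcription factor gene Mycn at 3.28-fold (adjusted p = 1.62e-06). Those that fell were Hhip, a decoy receptor for Hedgehog ligands (-0.46, adjusted p = 0.0326), Bcl2, an inhibitor of cell death (-0.54), and the growth factor gene Igf2 (-0.78). The list did not pass the test (adjusted p = 0.210), with a median of -0.03 and a mean of 0.47, and was called by fry (adjusted p = 0.00310) and with a sex covariate (adjusted p = 0.0420). Over all alternatives its adjusted p ran from 0.00310 to 0.596.

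Among 27 Hedgehog pathway components, 7 rose, 3 fell and 17 did not pass in Sufu KO, with 7 higher and 5 lower when adjusted over the list alone. Beside Gli2, the kinase gene Stk36 rose 1.34-fold (adjusted p = 0.00103). The 3 that fell were Sufu, Spop and Fbxw11, a substrate receptor of an SCF ubiquitin ligase (-0.35, adjusted p = 0.0102). The list did not pass (adjusted p = 0.595).

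Genes of the granule neuron lineage split by stage in Sufu KO. Of 11 progenitor genes, 7 rose, 0 fell and 4 did not pass, with 8 higher when adjusted over the list alone. Atoh1, the transcription factor that specifies granule neuron progenitors, rose 2.83-fold (95% confidence interval of the log2 difference 1.08 to 1.93, adjusted p = 0.000183). Insm1, a zinc finger factor of neuronal progenitors, rose 2.72-fold, and Barhl1, a homeobox factor of the lineage, 2.05-fold. The progenitor list had adjusted p = 2.74e-06, and adjusted p = 0.140 with an estimated correlation. Newborn and migrating granule neuron genes rose in 14 of 18 cases, also 14 when adjusted over the list alone, led by the transcription factor gene Nhlh1 at 3.57-fold and Igfbpl1 at 4.31-fold. That list reached adjusted p = 3.81e-11, and adjusted p = 0.138 with an estimated correlation.

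Mature granule neuron genes moved the other way in Sufu KO: 12 of 18 fell, 1 rose and 5 did not pass, with the same counts when adjusted over the list alone. Calb2, a calcium-binding protein, fell 1.95-fold (adjusted p = 0.000112), Vsnl1, a neuronal calcium sensor, 1.86-fold, and Etv1, a transcription factor of granule neuron maturation, 1.61-fold. The gene that rose was Reln, the secreted guidance protein reelin, which less mature granule neurons also make (0.39, adjusted p = 0.00141). The list test gave adjusted p = 3.85e-05, and adjusted p = 0.409 with an estimated correlation. Synaptic vesicle and postsynaptic density genes fell in 7 of 15 cases and 8 did not pass, with 9 lower and 1 higher when adjusted over the list alone. Camk2a, a synaptic kinase, fell 1.62-fold and Shank1, a postsynaptic scaffold, 1.31-fold. The synaptic list had adjusted p = 0.000457, and adjusted p = 0.302 with an estimated correlation.

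Lists of Purkinje cell and GABAergic interneuron genes were lower in Sufu KO beside these shifts. Levels in total RNA of a tissue are relative to the RNA of all its cells. A smaller share of a cell type therefore cannot be told apart from lower expression within it. This limit holds for every cell type list in every comparison. Of 14 Purkinje cell genes, 10 fell, 1 rose and 3 did not pass, with the same counts when adjusted over the list alone (list adjusted p = 6.66e-05, and adjusted p = 0.138 with an estimated correlation). Calb1, a calcium buffer of Purkinje cells, fell 1.60-fold, while Lhx1, a homeobox gene of their development, rose 1.68-fold. Of 11 GABAergic interneuron genes 9 fell and 2 did not pass, again 9 when adjusted over the list alone (list adjusted p = 2.26e-08, and adjusted p = 0.0624 with an estimated correlation). Pvalb, the calcium-binding protein parvalbumin, fell 2.02-fold (adjusted p = 1.86e-05) and Tfap2b, a transcription factor of interneuron precursors, 2.01-fold.

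Some glial, vascular and meningeal lists were also lower in Sufu KO. All 14 mature oligodendrocyte genes fell, likewise 14 when adjusted over the list alone, among them Mal, a myelin proteolipid, 1.91-fold, and Aspa, an enzyme of acetylaspartate breakdown, 1.74-fold (list adjusted p = 3.41e-09, and adjusted p = 0.160 with an estimated correlation). Of 14 Bergmann glia and astrocyte genes, 11 fell, 1 rose and 2 did not pass, the same when adjusted over the list alone (list adjusted p = 2.53e-06, and adjusted p = 0.155 with an estimated correlation). Beside Gdf10, the homeodomain gene Hopx fell 1.68-fold, and the riser was the GABA transporter gene Slc6a11 (0.54). Endothelial and pericyte genes fell in 6 of 15 cases, also 6 when adjusted over the list alone, among them Vtn, the adhesive protein vitronectin, 1.69-fold and Pdgfrb, a pericyte growth factor receptor, 1.30-fold (list adjusted p = 0.000558, and adjusted p = 0.155 with an estimated correlation). Meningeal fibroblast genes fell in 6 of 10 cases, or 8 when adjusted over the list alone, with Slc6a13, a GABA transporter, 1.39-fold lower and Ranbp3l 1.44-fold lower (list adjusted p = 0.000593, and adjusted p = 0.155 with an estimated correlation).

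Glycolysis genes fell in 9 of 14 cases in Sufu KO, or 10 when adjusted over the list alone, including Eno2, the neuronal enolase, 1.88-fold, and Slc2a1, the main glucose transporter of the blood-brain barrier, 1.43-fold. Its list test gave adjusted p = 0.000146, and adjusted p = 0.155 with an estimated correlation. Oligodendrocyte precursor genes (1 higher, 5 lower of 10, or 1 and 6 when adjusted over the list alone) did not pass the list test, at adjusted p = 0.0503. Pdgfra, the growth factor receptor of these precursors, was the riser, at 1.14 log2 units (adjusted p = 7.12e-06), and Olig1, Sox10, Enpp6, Lhfpl3 and Neu4 fell. The microglia list (C1qb and Cd68, 2 higher of 17, also 2 when adjusted over the list alone) had adjusted p = 0.0778, and choroid plexus (Kl, Sostdc1 and Otx2, 3 higher of 9, likewise 3 when adjusted over the list alone) 0.104; these 3 lists passed under some alternatives. Wnt targets (3 higher, Axin2, Nkd1 and Lgr5, and 1 lower, Wif1, of 10) and Notch genes (1 higher, Notch2, and 1 lower, Hey2, of 10) kept those counts when adjusted over the list alone, with list adjusted p values of 0.331 and 0.688. p53 targets (2 higher, Trp53inp1 and Eda2r, and 3 lower, Phlda3, Zmat3 and Perp, of 13) and brainstem and midbrain neuron genes (Slc17a6 higher and Ddc lower of 10) did so too, at 0.609 and 0.835. The p53 list had a median of -0.05 and a mean of 0.01. In all, 13 of 22 lists were called with the preset correlation and 0 with an estimated one, where 6 had an unadjusted p under 0.05; fry called 15.

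The comparison of the tumours labelled Ptch1 KO with wildtype cerebellum asks what sets this tumour tissue apart from normal tissue of the same age. Sex differed here too, with high Xist on 3 wildtype arrays and 1 tumour array, and the labels give no strain. Cdk6, a kinase that drives G1 progression, rose 16.8-fold (log2 difference 4.07 ± 0.11, SE, n = 3 per group, limma adjusted p = 1.25e-09). Olig3, a transcription factor of hindbrain progenitors, rose 19.7-fold (4.30 ± 0.15, adjusted p = 3.16e-09), Mki67 11.8-fold and Kif11, a spindle motor, 11.7-fold. Prm1 was 22.5-fold higher (4.49 ± 0.11, adjusted p = 3.47e-10). Among the genes that fell furthest, Fam107a fell by 3.70 ± 0.25 log2 units (adjusted p = 1.64e-07). St8sia5, a sialyltransferase that makes gangliosides, was 7.08-fold lower, Kcnip4, a potassium channel partner, 6.73-fold, and Cbln3, a secreted synaptic protein of granule neurons, 6.56-fold. Klk1b22, a kallikrein protease, fell 12.9-fold (adjusted p = 0.000427), and its level differed among the Sufu KO arrays, from 4.80 to 8.38. Genes higher in the tumours numbered 3606 and genes lower 4038, of which 560 and 657 differed by at least 1 log2 unit.

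Of 14 Hedgehog targets, 10 rose, 2 fell and 2 did not pass in the tumours, with the same counts when adjusted over the list alone. Beside Gli1, Ptch1 and Cdk6, the list held Mycn at 6.95-fold (2.80 ± 0.11, SE, adjusted p = 5.26e-09) and Ccnd2 at 5.66-fold. The 2 that fell were Igf2 (-0.53) and the homeobox gene Nkx6-2 (-0.45). The list test gave adjusted p = 2.49e-05, and adjusted p = 0.195 with an estimated correlation. Hedgehog pathway components rose in 13 of 27 cases, fell in 6 and did not pass in 8, with 13 higher and 7 lower when adjusted over the list alone. Smo, the receptor component that Ptch1 holds inactive, rose 2.37-fold (adjusted p = 4.77e-07). For the components the test gave adjusted p = 0.0401, and adjusted p = 0.208 with an estimated correlation. That call also ended without Sufu and Ptch1 (adjusted p = 0.0776) and with a filter at the array median (adjusted p = 0.0519), in a range over all alternatives from 0.000371 to 0.208.

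Every tested gene of mitosis (27) and of DNA replication and G1/S (30) rose in the tumours, with the same counts when adjusted over the list alone. Cenpe rose 6.81-fold, Plk1, a mitotic kinase, 6.41-fold, Mcm7 6.23-fold, Mcm5 4.77-fold, and Chaf1b, a histone chaperone of replication, 7.56-fold. Their list tests gave adjusted p = 5.29e-22 for mitosis and adjusted p = 4.91e-21 for replication, and for both adjusted p = 0.195 with an estimated correlation.

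Granule neuron progenitor genes rose in 9 of 11 cases in the tumours, with 1 fallen and 1 not passing, and the same when adjusted over the list alone. Atoh1 rose 10.7-fold (3.41 ± 0.20, SE, adjusted p = 5.66e-08), Insm1 3.66-fold and Barhl1 3.13-fold, while the zinc finger gene Zic2 fell (-0.34, adjusted p = 0.00669). The progenitor list test gave adjusted p = 0.000453, and adjusted p = 0.195 with an estimated correlation. Of 18 newborn and migrating granule neuron genes, 13 rose, 3 fell and 2 did not pass, the same when adjusted over the list alone. Nhlh1 rose 4.50-fold and Igfbpl1 4.68-fold, while Rbfox3, the neuronal splicing factor NeuN (-0.74), Stmn2, a microtubule regulator of neurites (-0.58), and Plxna2, a semaphorin receptor (-0.40), fell. Here the adjusted p was 0.000581, and adjusted p = 0.279 with an estimated correlation. Mature granule neuron genes fell in 17 of 18 cases and Reln rose (0.18, adjusted p = 0.0461), the same when adjusted over the list alone. Vsnl1 fell 4.97-fold, Calb2 4.77-fold and Etv1 3.43-fold (list adjusted p = 2.00e-09, and adjusted p = 0.208 with an estimated correlation).

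Purkinje cell, GABAergic interneuron and synaptic lists were lower in the tumours. Of 14 Purkinje cell genes 11 fell and 3 rose, the same when adjusted over the list alone, with Calb1 3.65-fold lower and Pcp2, a G protein modulator of Purkinje cells, 3.46-fold lower (list adjusted p = 0.000145, and adjusted p = 0.195 with an estimated correlation). The 3 risers were the transcription factor genes Foxp2 (1.54), Lhx1 (1.07) and Ebf2 (0.88), which other cells of the hindbrain also express. GABAergic interneuron genes fell in 10 of 11 cases, likewise 10 when adjusted over the list alone, with Pvalb 5.59-fold lower (adjusted p = 5.26e-09) and Tfap2b 3.98-fold lower (list adjusted p = 1.09e-07, and adjusted p = 0.0808 with an estimated correlation). Of 15 synaptic vesicle and postsynaptic density genes 12 fell, also 12 when adjusted over the list alone, with Camk2a 3.81-fold lower and Shank1 2.89-fold lower (list adjusted p = 1.09e-07, and adjusted p = 0.195 with an estimated correlation).

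Non-neuronal markers moved in both directions in the tumours. All 14 mature oligodendrocyte genes fell, likewise 14 when adjusted over the list alone, among them Cldn11, a myelin tight junction protein, 4.99-fold and Mal 4.91-fold (list adjusted p = 3.75e-10, and adjusted p = 0.195 with an estimated correlation). Bergmann glia and astrocyte genes fell in 11 of 14 cases, or 12 when adjusted over the list alone, with Gdf10 3.99-fold lower, Hopx 2.58-fold lower and Slc6a11 the only riser at 1.34 log2 units (list adjusted p = 0.000127, and adjusted p = 0.195 with an estimated correlation). Endothelial and pericyte genes fell in 11 of 15 cases, again 11 when adjusted over the list alone, by 1.35-fold for Pdgfrb and 1.45-fold for the junction protein gene Esam (list adjusted p = 0.00164, and adjusted p = 0.195 with an estimated correlation). Microglia and macrophage genes rose in 9 of 17 cases and 1, Siglech, fell, or 10 and 1 when adjusted over the list alone. C1qb, a complement component, rose 2.35-fold (adjusted p = 1.24e-06) and Cd68, a lysosomal protein of macrophages, 2.04-fold (list adjusted p = 0.000907, and adjusted p = 0.195 with an estimated correlation).

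Choroid plexus genes rose in 3 of 9 cases in the tumours, also 3 when adjusted over the list alone, namely Clic6, an intracellular chloride channel, 2.08-fold, Otx2, a homeobox gene also active in granule neuron progenitors, 1.85-fold, and Kl (0.37). Ttr, the transport protein that choroid plexus makes in bulk, read 1.53 log2 units higher without passing (adjusted p = 0.191) and was chosen after its value was seen. The list had adjusted p = 0.0401, and adjusted p = 0.422 with an estimated correlation. The call was lost with array weights (adjusted p = 0.0659). It was also lost without wildtype replicate 1 (0.0801) or 3 (0.0520) and without tumour replicate 2 (0.0529) or 3 (0.0861), and over all alternatives the adjusted p ran from 0.00704 to 0.422.

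Of 14 glycolysis genes 11 fell and 2 rose in the tumours, the same when adjusted over the list alone. Eno2 fell 5.10-fold, while the hexokinase genes Hk2 (2.74-fold) and Hk1 (0.37 log2 units) rose. The glycolysis test gave adjusted p = 0.000271, and adjusted p = 0.195 with an estimated correlation. Lists that did not pass were oligodendrocyte precursor (4 higher, 2 lower of 10, or 5 and 2 when adjusted over the list alone) and Notch signalling (5 and 1 of 10, the same when adjusted over the list alone), both at adjusted p = 0.142. Meningeal fibroblast (1 and 4 of 10) stood at 0.170 and brainstem and midbrain neuron (1 and 1 of 10) at 0.638. p53 targets (3 and 5 of 13, or 4 and 5 when adjusted over the list alone) and Wnt targets (2 and 2 of 10) both stood at 0.886. Counts of the meningeal, brainstem and Wnt lists were the same when adjusted over the list alone. Signs differed between median and mean for p53 targets (-0.02 and 0.05) and Wnt targets (0.02 and -0.08). Members of these lists that rose were Pdgfra, Cspg4, Olig2 and Lhfpl3 (precursor), Hes1, Notch2, Dll3, Jag1 and Nrarp (Notch), Lum (meningeal), Slc17a6 (brainstem), Trp53inp1, Eda2r and Btg2 (p53), and Nkd1 and Rnf43 (Wnt). Those that fell were Sox10 and Enpp6, Hey2, Slc6a13, Foxc1, Ranbp3l and Bmp6, Ddc, then Ccng1, Phlda3, Zmat3, Plk2 and Perp, and last Sp5 and Wif1, with the lists in the same order. In all, 16 of 22 lists were called with the preset correlation and 0 with an estimated one, where 4 had an unadjusted p under 0.05; fry called 19.

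**Figure D2:**
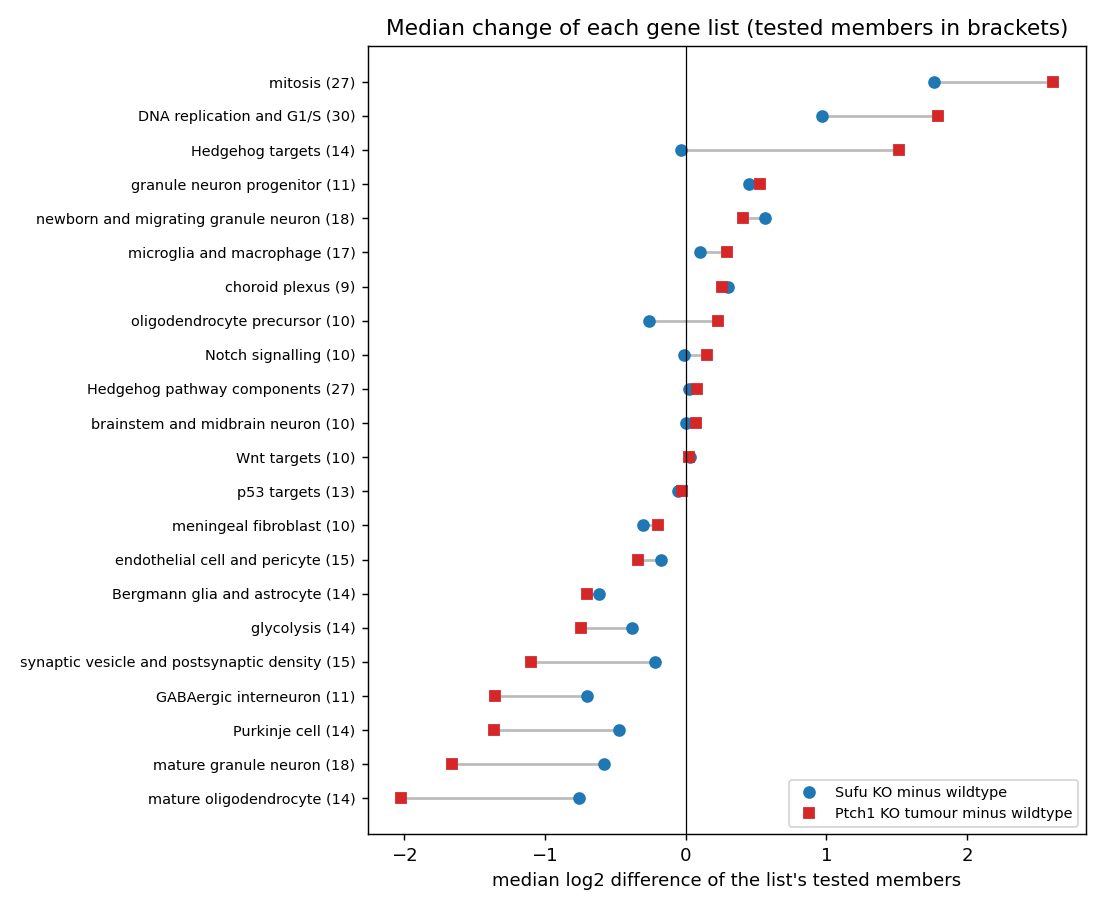
Median log2 difference from wildtype of the tested members of each of 22 gene lists (members in brackets), as circles for Sufu KO and squares for the tumours labelled Ptch1 KO, with a grey line joining the pair. The mitosis list stood at 1.77 and 2.61, and the Hedgehog target list at -0.03 and 1.52.

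The direct comparison of the tumours with Sufu KO cerebellum asks where the mutants differ. All samples of 1 group were tumour and all of the other cerebellum, so genotype cannot be told apart from tissue in any of these differences. The labels give no strain here either. Gli1 was 3.81-fold higher in the tumours (log2 difference 1.93 ± 0.12, SE, n = 3 per group, limma adjusted p = 1.81e-06), Cdk6 4.19-fold (adjusted p = 6.66e-07), Ptch1 2.12-fold and Hhip 1.86 log2 units (adjusted p = 4.80e-06). Hsd11b2, an enzyme that inactivates glucocorticoids and a Hedgehog target, was 4.22-fold higher, and Gli2 1.45-fold higher (adjusted p = 0.00779). Of 14 Hedgehog targets, 11 were higher, 0 lower and 3 did not pass, with 12 higher and 1 lower when adjusted over the list alone. The list test gave adjusted p = 8.09e-10, and adjusted p = 0.109 with an estimated correlation. Of 16323 genes, 1991 were higher and 2855 lower in the tumours than in Sufu KO, with 123 and 184 of them at least 1 log2 unit apart.

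Olig3 (5.65-fold), Rbp4, a retinol carrier (4.88-fold), and Lrig3, a membrane protein that modulates growth factor receptors (4.38-fold), were also among the genes furthest above Sufu KO. Islr2, a neuronal membrane protein, was 4.21-fold higher (adjusted p = 0.00120) with SDs of 0.62 in the tumours and 0.89 in Sufu KO. Furthest below were Mid1, a microtubule-bound ubiquitin ligase (3.97-fold, adjusted p = 0.00108), Fam107a (3.92-fold) and St8sia5 (3.54-fold). Mid1 ranged from 8.13 to 9.90 among the wildtype arrays. The myelin genes Mag and Mobp were 3.36-fold and 3.33-fold lower in the tumours.

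Hedgehog pathway components were higher in 8 of 27 cases and lower in 1 between the mutants, the same when adjusted over the list alone. Smo was 1.60-fold higher (adjusted p = 0.000212) and Sufu, the targeted gene, 3.52-fold higher, while Disp2, of the family that releases Hedgehog ligands, was 1.82-fold lower. That list had adjusted p = 0.0132, and adjusted p = 0.153 with an estimated correlation. Mitosis genes were higher in all 27 cases, also 27 when adjusted over the list alone, with Kif11 at 2.48-fold, Cenpe at 2.05-fold and Plk1 at 1.96-fold. Of 30 replication genes 28 were higher, or 30 when adjusted over the list alone, with Chaf1b at 2.39-fold, Mcm5 at 1.99-fold and Mcm7 at 1.90-fold. These lists had adjusted p = 6.48e-18 and adjusted p = 3.46e-19 in that order, and both had adjusted p = 0.153 with an estimated correlation.

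Mature granule neuron genes were lower in the tumours than in Sufu KO in all 18 cases, also 18 when adjusted over the list alone. Slc17a7, the vesicular glutamate transporter of granule neurons, was 2.52-fold lower (adjusted p = 4.71e-05), Calb2 2.44-fold and Etv1 2.14-fold (list adjusted p = 5.36e-13, and adjusted p = 0.153 with an estimated correlation). Progenitor genes went both ways, 4 higher and 3 lower of 11, the same when adjusted over the list alone, and the list did not pass (adjusted p = 0.167). Atoh1 was 3.77-fold, Cxcr4, a chemokine receptor of progenitors, 1.89-fold and Barhl1 1.53-fold higher, as was Insm1 (0.43 log2 units), while Mfap4 (-0.57), Zic2 (-0.37) and Zic5 (-0.28) were lower. Newborn granule neuron genes (3 higher, Nhlh1, Nhlh2 and Nfia, and 6 lower of 18, or 4 and 7 when adjusted over the list alone) did not pass either, at adjusted p = 0.296.

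Purkinje cell, interneuron and synaptic lists were lower in the tumours than in Sufu KO. Purkinje cell genes were lower in 11 of 14 cases and higher in 3 (Foxp2, Lhx1 and Ebf2), the same when adjusted over the list alone, with Ppp1r17, a phosphatase inhibitor, 3.24-fold and Pcp2 2.42-fold lower (list adjusted p = 2.39e-05, and adjusted p = 0.109 with an estimated correlation). GABAergic interneuron genes were lower in 9 of 11 cases, again 9 when adjusted over the list alone, with Pvalb 2.77-fold and Tfap2b 1.98-fold lower (list adjusted p = 1.49e-07, and adjusted p = 0.0868 with an estimated correlation). Synaptic genes were lower in 13 of 15 cases, also 13 when adjusted over the list alone, among them Camk2a (-1.24) and Shank1 (-1.15) (list adjusted p = 1.09e-09, and adjusted p = 0.153 with an estimated correlation).

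The 2 oligodendrocyte lists differed in direction between the mutants. Mature oligodendrocyte genes were lower in the tumours in 13 of 14 cases, likewise 13 when adjusted over the list alone, with Mog, a myelin surface protein, 3.20-fold and Cldn11 2.86-fold lower (list adjusted p = 1.24e-10, and adjusted p = 0.153 with an estimated correlation). Precursor genes were higher in 7 of 10 cases, or 7 higher and 1 lower when adjusted over the list alone, with Pdgfra 2.34-fold and Lhfpl3 1.89-fold higher (list adjusted p = 6.10e-05, and adjusted p = 0.153 with an estimated correlation). Microglia genes were higher in 7 of 17 cases and lower in 1 (Siglech), the same when adjusted over the list alone, with C1qb 1.63-fold and the lysosomal protease gene Ctss 1.46-fold higher (list adjusted p = 0.000242, and adjusted p = 0.153 with an estimated correlation).

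Glycolysis genes were lower in the tumours than in Sufu KO in 9 of 14 cases and higher in 1, or 10 and 2 when adjusted over the list alone. Eno2 was 2.72-fold lower and Hk2, the hexokinase of growing cells, 2.44-fold higher (list adjusted p = 0.00195, and adjusted p = 0.197 with an estimated correlation). Of 10 Notch genes 2 were higher, also 2 when adjusted over the list alone, namely Jag1, a Notch ligand, 1.96-fold, and Hes1, a Notch target, by 0.21 log2 units (list adjusted p = 0.0175, and adjusted p = 0.190 with an estimated correlation). The Hes1 call (adjusted p = 0.0246) ended when tumour replicate 1 or 2 or Sufu KO replicate 2 or 3 was left out, at adjusted p = 0.0718, 0.0858, 0.0608 and 0.0631, in a range over all alternatives from 0.00210 to 0.0858. Lists that did not pass were Bergmann glia and astrocyte (1 higher, 5 lower of 14, or 1 and 8 when adjusted over the list alone) at adjusted p = 0.0688, endothelial and pericyte (0 and 3 of 15) at 0.235, choroid plexus (1 and 0 of 9) at 0.259 and meningeal fibroblast (2 and 1 of 10, or 3 and 2 when adjusted over the list alone) at 0.259. Wnt targets (0 and 3 of 10, or 1 and 3 when adjusted over the list alone) stood at 0.366, brainstem and midbrain neuron (0 and 1 of 10) at 0.633 and p53 targets (1 and 2 of 13) at 0.693. The endothelial, choroid plexus, brainstem and p53 counts were the same when adjusted over the list alone. Members of these lists higher in the tumours were Slc6a11 (Bergmann glia), Clic6 (choroid plexus), Lum and Col1a1 (meningeal) and Eda2r (p53). Those lower were Hopx, Fabp7, S100b, Timp4 and Slc4a4 (Bergmann glia), Esam, Eng and Slco1a4 (endothelial), Bmp6 (meningeal), Axin2, Sp5 and Lgr5 (Wnt), Ddc (brainstem), and Plk2 and Perp (p53). In all, 13 of 22 lists were called with the preset correlation and 0 with an estimated one, where 6 had an unadjusted p under 0.05; fry called 14.

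Both mutants moved many genes in 1 direction. Higher in both against wildtype were 1839 genes, among them Mki67, Mycn, Cdk6 and Prm1, where independent lists would share 468.8. Lower in both were 1863 genes, among them Fam107a, Gdf10 and Calb1, where independent lists would share 501.7. Opposite directions were seen for 37 genes, against 973.0 for independent lists. Of the 3702 genes changed in the same direction, 3250 had the larger change in the tumours, 2068 of them past the threshold in the direct test. A larger change in Sufu KO past that threshold was seen for 52. Sufu and Hhip were among the 37, as were Smad3, a signal transducer of TGF-beta (-0.86 in Sufu KO and 0.23 in the tumours), and Cxcl14, a chemokine (0.50 and -0.88), both chosen after their values were seen.

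Across genes, which are not independent replicates, the differences from wildtype in the mutants correlated at 0.864 (Pearson). With unchanged groups simulated against the same wildtype arrays the correlation was 0.501 on average, between 0.448 and 0.565 in 100 draws, and 0 genes were called in both by limma. Unchanged groups give almost no calls by design, so that 0 does not measure what shared controls add to the shared calls. The covariance was 0.146 against a simulated 0.00535, a difference of 0.141. The 3 wildtype arrays cannot be split into sets of at least 2, so part of the excess in shared calls may come from the shared controls.

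**Figure D3:**
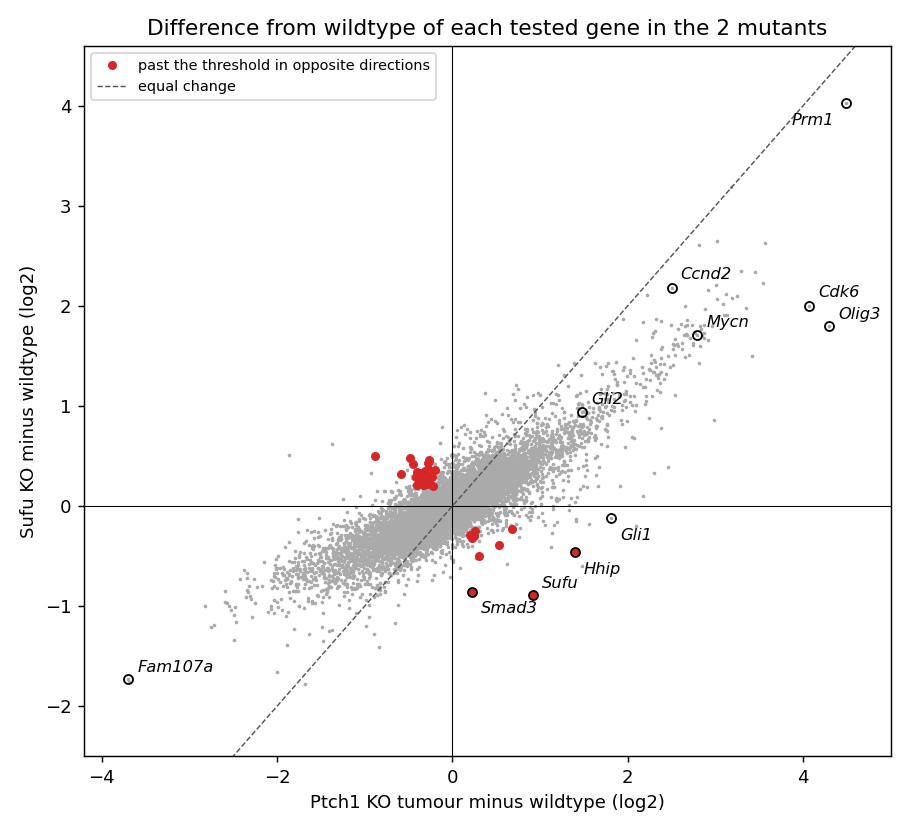
Log2 difference from wildtype of each of 16323 tested genes in the tumours labelled Ptch1 KO (horizontal) and in Sufu KO (vertical); each dot is a gene, the dashed line marks equal change and filled red circles are the 37 genes past the threshold in opposite directions. Of 3702 genes changed in the same direction 3250 had the larger change in the tumours, and Hhip, Sufu and Smad3 lie in the lower right quadrant.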

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

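Every test in this part except the splits of the arrays was chosen after the result was seen. A difference between groups set apart 37 genes that moved in opposite directions in the mutants against the same wildtype arrays, a selection that by itself leads to a difference between the mutants. Of single genes, Gli1, Hhip and Sufu were higher in the tumours labelled Ptch1 KO than in Sufu KO by 1.93, 1.86 and 1.81 log2 units in the direct test. Signals also appeared in probe sets that entered no comparison of the report. Among 1621 probe sets of several genes, 314 passed the threshold for Sufu KO against wildtype, 564 for the tumours against wildtype and 264 between the mutants. Among 12146 probe sets without annotation the counts were 881, 2227 and 924. These are smaller shares than among the genes tested, of which 25.4%, 46.8% and 29.7% were called in that order. Unlike those genes, the probe sets were not filtered for dim values.

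Gli1, Hhip and Ptch1, targets that feed back on the Hedgehog pathway, rose in the tumours (1.81, 1.40 and 1.02 log2 units) and not in Sufu KO, although Mycn, Sfrp1, Ccnd2 and Cdk6 rose in both. A smaller share of the same cells as in the tumours was tested by mixing the wildtype and tumour levels at the lowest share that 3 lists gave, 0.391 from replication (mitosis 0.436, mature granule neuron 0.505). Sufu KO lay below that mixture by -1.12 for Gli1, -1.19 for Hhip and -0.55 for Ptch1 (log2), where Mycn (-0.03) and Sfrp1 (0.04) lay on it, Hsd11b2 (-1.11), Cdk6 (-0.85) and Ccnd1 (-0.57) below it and Ccnd2 (0.68) above it; Bcl2 (-0.55) and Igf2 (-0.60), which did not rise in the tumours, lay as far below it as Ptch1. Of 560 genes at least 1 log2 unit higher in the tumours, 6, 4 and 35 lay as low as Gli1, Hhip and Ptch1 or lower. These 3 genes were picked because they did not rise in Sufu KO, so a place below the mixture followed from the choice. The test therefore does not decide on a smaller share. It shows only that 1 share did not give the levels of all these targets. Genotype and tissue, since 1 mutant group is tumour and the other cerebellum, stay open and untested.

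Prm1, a gene of sperm chromatin, averaged 5.94 in wildtype, 9.97 in Sufu KO and 10.4 in the tumours. Other spermatid genes argue against a spermatid programme or germ cell RNA, as the larger of their 2 median log2 differences from wildtype was -0.0020. Sex was argued against by the mutant arrays with high Xist, the lower of which stood 4.004 log2 units above the highest wildtype array. A candidate explanation is a transgene that carries Prm1 sequence: the lowest mutant array lay 3.73 above the highest wildtype array, while the neighbours Prm2, Prm3 and Tnp2 (order from assembly GRCm38.p6) lay within 0.104 of wildtype in Sufu KO and the tumours. The labels name no transgene, so this remains a hypothesis.

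A set of 9 probe sets shared by Gm3893 and its copies, none of which entered a comparison, was lowest in Sufu KO, at 7.31 ± 0.10 (log2, SD, n = 3) against 11.86 ± 0.12 in wildtype and 10.76 ± 0.14 in the tumours. The difference from wildtype was -4.55 in Sufu KO and -1.10 in the tumours. The fall was not of equal size in the mutants, with a gap of 3.45 between the tumours and Sufu KO. The set was picked after its low level in Sufu KO was seen, so a gap followed from the choice. It therefore does not decide on a response shared by both mutants. Strain background cannot be told apart from genotype: every Sufu KO array lay at least 3.24 below every other array, and the labels give no strain.

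For the counts of called genes, the 10 splits of the 6 arrays of a comparison are too few for a share under 0.05. With limma on those 6 arrays the real split called 4212 genes for Sufu KO against wildtype, 7780 for the tumours against wildtype and 4335 between the mutants, and in each the highest other split called 0. In 1 of the 10 splits, the real one, the count was as large. Every other split put arrays of both groups on each side. A difference between the groups then widens the spread within each side and largely cancels between them. The count of 0 therefore followed in large part from the design and does not measure how many calls chance gives. At an unadjusted p under 0.05 the real splits held 5889, 8613 and 5862 genes, and the highest other splits 1236, 436 and 1369.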

How the results depend on the processing

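The sex covariate, the fit without X and Y chromosome genes and the fit of arrays with high Xist were chosen after the data were seen; the other alternatives were planned. The 142 results for genes named by the fixed rule kept their direction and side of the threshold in 2828 of 2834 alternatives, and 6 calls were lost, for Galnt15 in 2 and Hes1 in 4, at the values given in the report. Most of these genes were picked from the same arrays for a small p or a large difference, so this says little of other calls. Members named for small counts were not run under the alternatives. Of 1452 alternatives for 66 list results 1372 kept theirs, 49 lost the call, 31 gained it and 0 reversed. Of 42 called lists 40 stayed past the threshold in every alternative except the estimated correlation, the exceptions being Hedgehog pathway components and choroid plexus in the tumours against wildtype, the latter at the values given in the report. Dim genes lie near background, there are no detection calls, and a pseudocount of 16 was not run because the values were already log2. Where no cause is named below, the cause was not tested.

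Genes higher and lower numbered 2122 and 2028 in Sufu KO against wildtype and 1991 and 2855 between the mutants, and with array weights 3712 and 3706, and 3699 and 4448; the correlation of the mutants' differences was then 0.817, and the weights' fit stopped before it converged. By construction, stricter thresholds gave fewer. A difference of at least 1 log2 unit left 186 and 36 in Sufu KO, 560 and 657 in the tumours and 123 and 184 between the mutants. An adjusted p of 0.01 left 1287 and 1208 in Sufu KO, and 1300 higher between the mutants. Arrays with high Xist gave 1063 and 1764 between the mutants, which says nothing of stability: each mutant group held 1 such array, assumed to vary like the 3 of wildtype, which gave all of the spread. The correlation with a sex covariate was 0.884.

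Leaving out each array in turn gave 1531 to 2359 genes higher and 1515 to 2214 lower in Sufu KO, 3096 to 3751 and 3583 to 4173 in the tumours, and 1435 to 2288 and 2251 to 2834 between the mutants. Genes shared by the mutants ran from 1358 to 2006 higher and 1408 to 1995 lower, and the correlation from 0.836 to 0.871. With the replicate number as a block, counts were 1979 and 2010, 3530 and 3990, and 1877 and 2749. The block also brought oligodendrocyte precursor (adjusted p = 0.0426) and microglia (0.0341) past the threshold in Sufu KO, where ranges over all alternatives were 0.00920 to 0.326 and 0.0134 to 0.438, and changed no other list call. Only 2 of 9 same-numbered pairs had deviations correlated over 0.1 (-0.313 to 0.352), so the numbers do not pair the arrays.

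An estimated correlation between genes left 0 lists called by camera in the 3 comparisons, where 6, 4 and 6 had an unadjusted p under 0.05 and fry called 15, 19 and 14. Adjusted p was then 0.140, 0.409, 0.138 and 0.138 for progenitor, mature granule neuron, replication and mitosis in Sufu KO. In the tumours it was 0.195 for Hedgehog targets, progenitor, replication and mitosis and 0.208 for Hedgehog components and mature granule neuron. Between the mutants it was 0.109 for Hedgehog targets and 0.153 for components, mature granule neuron, replication and mitosis. Hedgehog components in the tumours also missed the threshold with a filter at the array median (0.0519) and without Sufu and Ptch1 (0.0776), in a range of 0.000371 to 0.208. Hedgehog targets in Sufu KO were called by fry (0.00310) and with the sex covariate (0.0420), in a range of 0.00310 to 0.596.

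Several lists that did not pass camera with the preset correlation passed under other choices. Their adjusted p with that setting ran from 0.0503 (oligodendrocyte precursor in Sufu KO) to 0.366 (Wnt targets between the mutants). Oligodendrocyte precursor in Sufu KO passed with quantile normalization (0.0443), cyclic loess (0.0441), no filter (0.0358) or only the 2 groups compared (0.0292), and without Sufu KO replicate 2 (0.00920) or tumour replicate 1 (0.0403) or 3 (0.0307; range to 0.326). Microglia in Sufu KO passed with cyclic loess (0.0492), no filter (0.0491), a filter at the array median (0.0326), array weights (0.0134) or the sex covariate (0.0466), and without Sufu KO replicate 1 (0.0242; range to 0.438). Choroid plexus in Sufu KO passed with the sex covariate (0.00962) and without wildtype replicate 2 (0.0475) or Sufu KO replicate 2 (0.00306; range to 0.918). Between the mutants Bergmann glia passed with no filter (0.0373) or array weights (0.0375) and without Sufu KO replicate 1 (0.0463) or tumour replicate 3 (0.00609; range to 0.535), and choroid plexus with array weights (0.0128) and without Sufu KO replicate 3 (0.0438; range to 0.962). By fry alone passed Wnt targets in Sufu KO (0.0323) and between the mutants (0.0254), and in the tumours oligodendrocyte precursor (0.000973), meningeal fibroblast (0.00409) and Notch signalling (0.0155).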

Other observations

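All lists and genes in this part were chosen after the data were seen, the cholesterol list because Hmgcs1 and Msmo1 were among the 37 genes that moved in opposite directions in the mutants. List p-values were adjusted over the lists of this part alone, a smaller set than the planned lists, so the 2 sets of adjusted p are not comparable. Of 18 ribosomal protein genes, 9 rose in Sufu KO and 17 in the tumours, and 16 were higher in the tumours than in Sufu KO. Rpl4 rose by 0.72 and 1.09 log2 units, Rpl5 by 0.59 and 1.29 and Rps20 by 0.87 and 1.10 in Sufu KO and the tumours. The mitosis list moved with them, with medians of 1.77, 2.61 and 0.87 in Sufu KO against wildtype, the tumours against wildtype and the tumours against Sufu KO. The list test (camera) gave adjusted p = 9.39e-06, 1.38e-09 and 8.15e-10 in that order, and 0.266, 0.161 and 0.131 with an estimated correlation. Of 20 genes of Fanconi and homologous recombination repair, 15 rose in Sufu KO and 19 in the tumours, while 17 were higher and 1, Fancg (-0.38), lower between the mutants. Fancd2, the protein that marks crosslinked DNA for repair, rose by 1.01 and 2.10, Exo1, an exonuclease, by 1.10 and 2.28 and Brca1 by 0.97 and 1.68. Their list tests gave adjusted p = 7.44e-11, 5.30e-11 and 8.15e-10, and 0.196, 0.161 and 0.131 with an estimated correlation.

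Cholesterol synthesis genes differed between the mutants, in a comparison in which cell type lists also fell, with medians of -1.26 for mature oligodendrocyte and -1.10 for mature granule neuron. Of 16, 11 rose and 0 fell in Sufu KO, 2 rose and 6 fell in the tumours, and all 16 were lower in the tumours than in Sufu KO by limma. Fdft1, which commits farnesyl units to sterols, read 0.81 in Sufu KO and 0.39 in the tumours against wildtype and -0.42 between them. Srebf2, the transcription factor that drives the pathway, read 0.57, 0.21 and -0.36, and the demethylase gene Msmo1 0.33, -0.36 and -0.69. The list test gave adjusted p = 2.40e-05 in Sufu KO (0.110 with an estimated correlation), 0.467 in the tumours (where fry gave 0.0118) and 1.66e-08 between the mutants, which passed also with an estimated correlation (0.0336). Without Hmgcs1 and Msmo1, 14 of 14 were lower in the tumours than in Sufu KO (adjusted p = 3.15e-07, and 0.0353 with an estimated correlation). Leaving these genes out does not undo the choice of the list after the data were seen. Whether the list would pass beside the planned lists with an estimated correlation was not tested. Of 17 genes of voltage-gated potassium channels and their partner proteins, 10 fell in Sufu KO and 12 in the tumours. Between the mutants 12 were lower. Kcnc1, a channel of fast-spiking neurons, read -0.85 and -1.81 in Sufu KO and the tumours, and Kcna2 -0.67 and -1.70. Among the partners was Kcnip4, named in the report as 1 of the genes that fell furthest in the tumours. The list was not run without it. Kcnq5 (1.09 and 0.85) and Kcnb2 (0.85 and 0.49) rose in both mutants. Neuronal lists fell with them, with medians of -0.58, -1.66 and -1.10 for mature granule neuron and -0.70, -1.35 and -0.84 for GABAergic interneuron. The channel list had adjusted p = 0.000317, 1.89e-05 and 1.66e-08, and 0.196, 0.161 and 0.0651 with an estimated correlation.

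Axon guidance genes went both ways (8 higher, 7 lower of 27 in Sufu KO; 8 and 11 in the tumours; 4 and 13 between the mutants) and did not pass camera, at adjusted p = 0.635, 0.758 and 0.229, while fry gave 0.0229, 0.293 and 0.00439. Imprinted genes (2 and 3, 5 and 5, 4 and 3 of 18) and interferon response genes (3 and 0, 1 and 3, 1 and 4 of 16) did not pass camera either, where fry called imprinted genes in Sufu KO (0.0441) and interferon genes between the mutants (0.0103).

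Xist stood between 11.59 and 11.76 on the wildtype arrays, at 11.90 on Sufu KO replicate 3, at 11.97 on tumour replicate 2, and between 5.55 and 5.83 on the other 4 arrays. The Y-linked gene Eif2s3y was between 8.69 and 8.96 on those 4 and at most 4.21 elsewhere. Cwc22, a splicing factor gene, took 2 levels: 10.3 to 10.9 in wildtype, 8.21, 8.18 and 10.3 on the Sufu KO arrays in order of replicate, and 10.3, 8.43 and 8.27 on the tumour arrays. Klk1b22 read 8.38, 7.46 and 4.80 on the Sufu KO arrays, at most 5.14 on the tumour arrays and 8.21 to 8.98 in wildtype. Mid1 read 9.90, 8.13 and 9.81 in wildtype, 9.75 to 10.1 in Sufu KO and 7.68 to 8.13 in the tumours. Ccl19, a chemokine gene that lies beside Gm21158 in assembly GRCm38.p6, read 8.63 to 8.71 in wildtype, 7.35 to 7.44 in Sufu KO and 7.60 to 7.87 in the tumours. Of 4 globin probe sets of several genes, 2 were lower in the tumours than in wildtype (-1.33, adjusted p = 0.0202, and -1.34, adjusted p = 0.0155), and in Sufu KO the 4 read -0.73 to -0.87 without passing.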
